A study of Danio rerio with 12 samples.

How the data were processed

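RNA was sequenced from 12 pools of whole zebrafish embryos (Danio rerio). Healthy GFP-positive embryos were taken out of the chorion and kept from 23 hours after fertilization in DMSO, in 50 µM empagliflozin or in 50 µM canagliflozin. RNA was extracted at 27 hours, after 4 hours of treatment, from 5 embryos per sample, and each of the 3 groups had 4 samples. Libraries were made with a stranded mRNA kit and read as 50 bp pairs on an Illumina NovaSeq. The labels give group and replicate number, and no clutch, day or lane.

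The authors checked reads with FastQC, used the danRer10 genome build and worked in R 3.6.1. The read aligner, the gene counter and the gene filter are not given in the sources used here. The deposited normalized table holds a signal per gene and library that proved to be CPM (a gene's reads relative to library size) scaled by TMM, a factor that evens out composition between libraries. All values were whole read counts within 0.001 reads once multiplied by the library's effective size, and TMM factors recomputed in edgeR from the recovered reads matched those in the table, which ran from 0.939 to 1.03. The authors' comparison tables, named after the ROTS test, hold p-values and false discovery rates (p_value) and a log2 fold change equal to the difference of mean log2(CPM + 1). The deposited fold column is of another kind (other), a signed ratio made from the log2 value. The deposited group means are on the signal scale, and the SD columns beside them were not used. The authors' filtered tables hold genes with a false discovery rate under 0.05 and a log2 fold change of at least 1 in size, tested on the full tables.

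The table had 14134 genes, named by symbol, of which 1038 carried no Entrez ID. A gene was tested when its mean over the 12 libraries was at least 1 CPM, which left 11964 genes and set aside 2170. Gene positions are not given in the tables and no build was converted. Recovered reads per library ran from 16149682 to 27842375, so that 1 read was 0.0363 to 0.0621 CPM and a count of 0 allows up to 3 reads, or 0.109 to 0.186 CPM. These floors cover counting error alone, since reads without molecular identifiers are not independent molecules. No 2 libraries of a group were copies of each other: the chi-square per degree of freedom between pairs ran from 5.05 to 39.3.

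Before the data were examined, the groups, the tests, the gene lists, the rule for named genes and the alternatives were fixed. Genes were compared with limma (3.58.1 in R 4.3.3; lmFit, then eBayes with a variance trend) on log2(CPM + 1), with a mean for each of the 3 groups in 1 fit, two-sided, and Benjamini-Hochberg adjustment over the genes tested in each comparison with a threshold of 0.05. Intervals are 95% intervals from that fit. Fold changes are on the CPM + 1 scale, which understates the change of genes with few CPM. Of 38 gene lists (pathways, complexes and marker genes of embryonic cell types), 37 had at least 3 tested genes; no gene of the list of mitochondrially encoded genes was in the table. Lists were tested with limma's camera at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry. The p-values measure the spread between pools whose clutches the labels do not give.

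Named genes were, in each comparison, the 12 with the largest rise and the 12 with the largest fall among genes past the threshold with a gene symbol; where fewer than 20 passed in all, those with the smallest unadjusted p up to 20; up to 12 in each direction from the authors' filtered tables; slc5a1, slc5a2 and the glucose transporter family slc2a; and up to 4 members with the smallest p from each list that passed. Not every gene that this rule selects is reported here. The response shared by both compounds was measured as a correlation and a covariance across genes, beside simulated unchanged groups, since both are set against the same 4 controls.

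Alternatives were pseudocounts of 0.1 and 5, no minimum and a minimum of 5 CPM, quantile normalization, median centring, the replicate number as a block, fits on the compared groups alone, no variance trend, robust variance, sample weights, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, an adjusted p threshold of 0.1, and each library left out in turn. After the data had been seen, leaving out control 4 and canagliflozin 4 together, and median centring for the lists, were added. The tests were checked on simulated counts with known changes. Percentages are of the changed genes whose simulated mean stayed at 1 CPM or more. At 2-fold, limma recovered 93.8%, 98.5% and 95.4% of these genes for empagliflozin against control, canagliflozin against control and empagliflozin against canagliflozin. In the same order it recovered 62.7%, 71.6% and 77.6% at 1.5-fold, and 10.6%, 8.96% and 14.9% at 1.25-fold. Genes varied independently in these counts, and no library deviated as a whole as control 4 and canagliflozin 4 did. The rates may therefore overstate what could be found in the real data.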

Results

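Transcript levels of whole zebrafish embryos were compared after 4 hours in DMSO, empagliflozin or canagliflozin, with 4 pools of 5 embryos per group. Both compounds are inhibitors of SGLT2, the sodium-glucose cotransporter encoded by slc5a2. Libraries held 16149682 to 27842375 reads, and the 50 most abundant genes took 19.9% to 22.7% of the reads of a library. Values are TMM-normalized CPM, given as mean ± SD over the 4 pools of a group.

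The 4 empagliflozin pools stood together on the principal axis of variation and apart from the other pools. That axis held 41.8% of the variance, with scores of 15.6 to 18.6 in empagliflozin. Control 4 scored 7.52 and canagliflozin 4 scored 5.95, while the other 3 controls and the other 3 canagliflozin pools lay between -17.9 and -8.92. The next axis held 15.4%, and canagliflozin 4 lay at -24.5 on it. Placed between its own group at 0 and empagliflozin at 1, over the genes called without it, control 4 stood at 0.677 and canagliflozin 4 at 0.534. The other controls stood at -0.158 to 0.107 and the other canagliflozin pools at -0.0925 to 0.0523. Each position has its own scale. Control 4 was placed over 3033 genes and the other controls over 268 to 540, with control 4 in their zero point. Canagliflozin 4 was placed over 4234 genes and the other canagliflozin pools over 1932 to 2197, with canagliflozin 4 in theirs. These 2 libraries are therefore given beside the gene groups below.

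**Figure D1:**
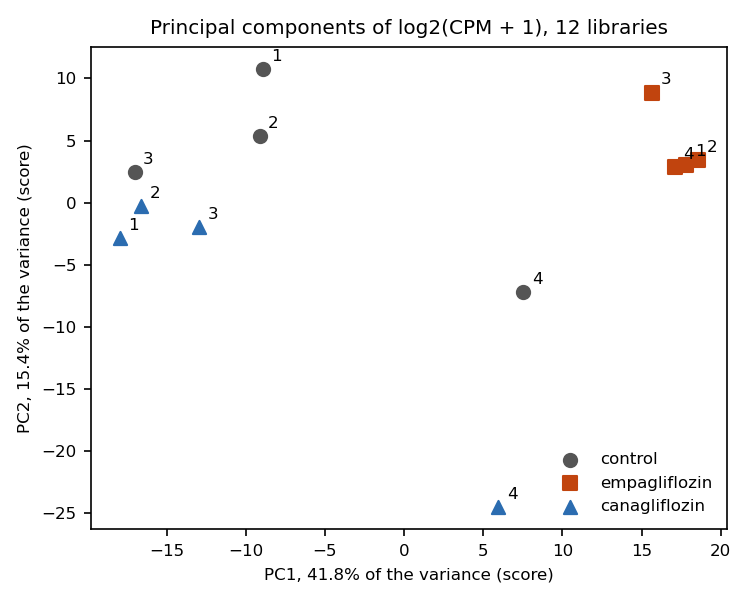
Principal component scores of the 12 libraries on log2(CPM + 1), by group, with replicate numbers beside the points. The empagliflozin libraries score 15.6 to 18.6 on the horizontal axis, and control 4 (7.52) and canagliflozin 4 (5.95) lie between them and the rest of their groups.

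Empagliflozin against control asks which transcripts differ after 4 hours in that compound. Some subunits of the mitochondrial respiratory chain, some markers of yolk syncytial layer and liver and some myeloid markers were lower in the empagliflozin pools, and some markers of neurons and neural progenitors were higher. As lists these passed at a preset correlation between genes, and with an estimated correlation 0 of 37 lists passed (adjusted p 0.454 to 0.785 for those that passed before). Other splits of the same libraries gave up to 15 lists, so that chance is not excluded for the 8 that passed. Among called genes the fall of largest size was in ankrd37, a hypoxia-inducible gene. It was at 3.87 ± 0.511 CPM in empagliflozin and 10.8 ± 0.734 in control (n = 4 each), 2.43-fold lower on the CPM + 1 scale. Most changes were small: the median log2 size among called genes was 0.39, and 7 called genes passed 2-fold on the CPM + 1 scale. Of 11964 genes tested, 1589 passed adjusted p of 0.05 in limma, 822 higher and 767 lower. In 2281 genes (19.1%) all 4 pools of a group lay on one side of all 4 of the other, against 2.86% by chance.

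The genes that fell had varied functions. For ankrd37 (Entrez 793783) the log2 fold change was -1.28, with a 95% interval of -1.55 to -1.01 and a limma adjusted p of 0.000341. cd36, a fatty acid uptake protein (Entrez 436636), stood at 5.19 ± 0.622 against 11.01 ± 2.46 CPM, a log2 change of -0.94. mia, which encodes a secreted cartilage protein, changed by -1.09, the cathepsin S gene ctssb.1 by -1.01 and the apolipoprotein gene apoa4a by -0.73. anapc16, of the anaphase-promoting complex, changed by -0.82, and the kinase gene pim2 by -0.78. In control 4, ankrd37 was 0.08 and cd36 0.50 above the other controls on the log2 scale, while anapc16 stood at -0.76, apoa4a at -0.51 and pim2 at -0.39 from them.

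Genes that rose included tfap2d, egr1 and crx, which encode transcription factors. tfap2d (Entrez 566838) was at 5.92 ± 0.261 CPM against 2.75 ± 0.258, a log2 change of 0.89 with a limma adjusted p of 0.00111. The immediate-early gene egr1 rose by 0.89, the photoreceptor homeobox gene crx by 0.81, atxn1a by 0.92 and raph1b by 0.83. Among called genes mansc1 had the largest rise, 1.198, from 44.0 ± 22.4 to 95.1 ± 13.2 CPM, with a limma adjusted p of 0.0266. In control 4 mansc1 stood 1.21 above the other controls, atxn1a 0.62 and raph1b 0.59, while tfap2d differed there by 0.01. The call of mansc1 was lost, with adjusted p of 0.0515 to 0.0805, whenever control 1, 2 or 3 or any of the 4 empagliflozin libraries was left out. Of 55 named genes that passed, 26 kept their call under every alternative. Among them were all those given with a value in this and the preceding paragraph, except mansc1. Some other named genes that passed lost their call in some alternatives and lay near empagliflozin in control 4. From the other controls, plgrkt stood at 0.78 there against 1.04 for empagliflozin, igfbp7 at 0.82 against 1.04 and rpa3 at -0.91 against -1.15. By contrast, egr1 stood at 0.18 against 0.93 and crx at 0.19 against 0.86.

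Some nuclear-encoded respiratory chain genes fell. Of 35 complex I subunits measured, 16 fell and 0 rose, with a median log2 change of -0.23 (camera adjusted p 0.00043; adjusted p = 0.454 with an estimated correlation). Adjusted over the list alone, 2 rose and 19 fell. Of 35 subunits of complexes II to V, 16 fell and 0 rose, with a median of -0.22 (camera adjusted p 0.000155; adjusted p = 0.462 with an estimated correlation). Adjusted over the list alone, 1 rose and 18 fell. Cytochrome c1, cyc1, was at 154 ± 9.33 CPM against 197 ± 13.9, a log2 change of -0.35, and cox4i1 changed by -0.33 and uqcrfs1 by -0.51. ndufa10 of complex I changed by -0.35, and without control 3 its adjusted p was 0.0503. In control 4 the median of complex I genes was -0.20 from the other controls and that of complexes II to V -0.19, against -0.29 and -0.27 for empagliflozin.

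Some markers of the nervous system rose. Of 29 neuron markers 9 rose and 0 fell, with a median of 0.18 (camera adjusted p 0.000715; adjusted p = 0.454 with an estimated correlation), and adjusted over the list alone 10 rose. elavl3, a marker of new neurons, was at 284 ± 11.5 against 220 ± 9.34 CPM, and elavl4 changed by 0.47. Of 13 markers of neural progenitors and glia, 5 rose and 0 fell, with a median of 0.21 (camera adjusted p 0.0259; adjusted p = 0.454 with an estimated correlation). Adjusted over the list alone, 6 rose and 1 fell. The eye and brain transcription factor genes pax6b and pax6a changed by 0.58 and 0.49. Of 20 lens and retina markers, 19 had a higher mean, but 1 rose by its own test, with a median of 0.20 (camera adjusted p 0.00532; adjusted p = 0.785 with an estimated correlation). Adjusted over the list alone, 1 rose and 0 fell. In control 4 the medians of these lists were 0.08 for neurons, -0.00 for neural progenitors and -0.08 for lens and retina from the other controls, against 0.15, 0.26 and 0.19 for empagliflozin.

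Some yolk and liver, myeloid and cell cycle genes fell. Of 19 markers of yolk syncytial layer and liver, 5 fell and 0 rose, with a median of -0.15 (camera adjusted p 0.0259; adjusted p = 0.785 with an estimated correlation), and adjusted over the list alone 7 fell. The transferrin gene tfa was at 1037 ± 133 against 1672 ± 251 CPM, serpina1l changed by -0.50 and apoa4b.1 by -0.54. All 14 myeloid markers had a lower mean and 3 fell, with a median of -0.21 (camera adjusted p 0.0275; adjusted p = 0.454 with an estimated correlation); adjusted over the list alone 3 fell. The lysozyme gene lyz changed by -0.48, and lost its call without control 1, 2 or 3 (limma adjusted p 0.0514, 0.051 and 0.0546). The myeloid markers mmp9 and mmp13a were at 92.0 and 50.4 CPM in control 3, against at most 13.7 and 1.97 in the other controls. Of 28 cell cycle genes, 5 fell and 1 rose, with a median of -0.08 (camera adjusted p 0.0452; adjusted p = 0.454 with an estimated correlation), and adjusted over the list alone 8 fell and 1 rose. Cyclin B1, ccnb1, changed by -0.31. In control 4 the yolk and liver median was 0.08, the myeloid median -0.10 and the cell cycle median -0.03 from the other controls, against -0.11, -0.27 and -0.09 for empagliflozin.

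The count of 1589 genes depended on which pool was left out. It was 540 without control 1, 316 without control 2, 268 without control 3 and 3033 without control 4. It was 733, 455, 495 and 770 without empagliflozin 1, 2, 3 and 4, and 2708 without canagliflozin 4, which enters only through the shared spread. Without control 4 and canagliflozin 4 together, an alternative added after seeing the data, 4246 genes passed, and 1584 of the 1589 were among them. All 1589 kept their sign in each of these fits. The lists that passed, 8 in all, came to 3 without control 3, 3 without control 4, 5 without empagliflozin 4 and 5 with quantile normalization. The lists of complex I, of complexes II to V and of neurons passed in each fit that left out a library. Without control 3 the adjusted p was 0.0575 for lens and retina, neural progenitors, cell cycle and yolk and liver, and 0.116 for the myeloid list. Without control 4 it was 0.0506 for the lens and retina, neural progenitor and myeloid lists, 0.080 for cell cycle and 0.0949 for yolk and liver. Without empagliflozin 4 it was 0.0548 for neural progenitors and 0.0829 for cell cycle and yolk and liver; the cell cycle list also missed without control 2 (0.0641), empagliflozin 3 (0.0519), canagliflozin 3 (0.05004) and canagliflozin 4 (0.0532), and with a minimum of 5 CPM (0.0512). With quantile normalization it was 0.0615 for the myeloid, neural progenitor and yolk and liver lists. Without control 4 and canagliflozin 4 together it was 0.0841 for the cell cycle, lens and retina, myeloid and neural progenitor lists and 0.167 for yolk and liver. With fry it was 0.165 for lens and retina and 0.105 for yolk and liver, while the hypoxia list (0.00414) and the list of gluconeogenesis and glucose-responsive genes (0.0222) passed. The authors' deposited table had 1901 genes under a false discovery rate of 0.05, of which 1398 were called here, and 8 in the filtered table. Of those 8, zgc:158463 did not pass here (log2 1.55, adjusted p 0.0992): it was at 7173, 3431, 923 and 1114 CPM in the empagliflozin pools and at 681 to 854 in the controls.

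Canagliflozin against control asks the same of the other compound at the same dose and time. Among the genes with the smallest unadjusted p were RNAs of crystallin gamma M2d, lens proteins, at lower values in the canagliflozin pools, and mcm4, a subunit of the replicative helicase, at a slightly higher value. crygm2d3 was at 18.9 ± 1.95 CPM against 31.5 ± 7.01 in control (n = 4 each; log2 -0.68, interval -0.94 to -0.42), and mcm4 at 342 ± 10.19 against 291 ± 2.18 (log2 0.23, interval 0.11 to 0.35). Neither passed, nor did any other gene: limma called 0 of 11964 genes, with 925 at an unadjusted p under 0.05 and a smallest adjusted p of 0.385. The pools of the groups did not overlap in 537 genes (4.49%), against 2.86% by chance. edgeR called 0 genes and DESeq2 24, with 11 higher and 13 lower. limma called 7 genes, all lower, without control 3, and 42 with sample weights, 10 higher and 32 lower.

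Crystallin copies and several neural genes were among those with the smallest unadjusted p. crygm2d5 had a log2 difference of -0.80, crygm2d21 of -0.79 and crygm2d8 of -0.67, and values of single copies are uncertain since the copies are near-identical. neurog1, a proneural transcription factor gene, differed by 0.46, olig2 by 0.31 and the importin gene kpnb3 by 0.30. atoh7, a transcription factor gene of retinal ganglion cells, was at 3.03 ± 0.402 against 7.23 ± 4.08 CPM, with controls of wide spread. In canagliflozin 4 neurog1 stood 0.40 above the other canagliflozin pools. The 95% intervals, which are not adjusted for the number of genes, had a median half-width of 0.22 on the log2 scale, and the larger differences given here did not pass either. The authors' deposited table had 3 genes under 0.05, cbln2b (log2 -0.28), mcm4 (0.23) and pet100 (-0.24), chosen for mention after their values were seen, and 0 in the filtered table.

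With canagliflozin against control, 6 lists passed at the preset correlation, with small medians, and 0 with an estimated correlation. Other splits of these libraries gave up to 14 lists, so that chance is not excluded for the 6. The cell cycle list had a median of 0.07 (camera adjusted p 0.000774; adjusted p = 0.416 with an estimated correlation), with 0 of 28 genes passing and 5 rising when adjusted over the list alone. Complexes II to V had a median of 0.10 (adjusted p 0.00227; adjusted p = 0.699 with an estimated correlation) and complex I of 0.06 (adjusted p 0.0259; adjusted p = 0.699 with an estimated correlation). Markers of pigment cells had a median of 0.07 (adjusted p 0.0266; adjusted p = 0.667 with an estimated correlation), with the neural crest gene sox10 at 0.34. Pronephros markers, of the embryonic kidney, had a median of 0.12 (adjusted p 0.0402; adjusted p = 0.507 with an estimated correlation). Lens and retina markers had a median of -0.14 (adjusted p 0.00743; adjusted p = 0.699 with an estimated correlation), with 2 falling and 1 rising when adjusted over the list alone. In the other 4 of these 6 lists, 0 genes rose or fell when adjusted over the list alone. The fry test passed 1 list, cell cycle. In control 4 the medians of cell cycle, complexes II to V, complex I, pigment cells, pronephros and lens and retina were -0.03, -0.19, -0.20, -0.05, -0.01 and -0.08 from the other controls, for both sets of complexes larger in size than the difference between groups. In canagliflozin 4 they were -0.06, -0.09, -0.08, 0.06, 0.11 and 0.18 from the other canagliflozin pools.

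These list calls changed with the pool left out. Of 6 lists, 2 passed without control 4, 3 without canagliflozin 3 and 10 lists in all without control 3. Without control 4 the adjusted p was 0.207 for complexes II to V, 0.334 for complex I, 0.161 for pigment cells and 0.061 for pronephros. Without control 2 it was 0.295 for lens and retina and 0.121 for pronephros; without canagliflozin 1 it was 0.143 for complex I and 0.0728 for lens and retina. Without canagliflozin 3 it was 0.0765 for lens and retina, pigment cells and pronephros, and without canagliflozin 4 it was 0.0781 for pigment cells and 0.329 for pronephros. It was 0.0775 for pronephros without control 1 and 0.0547 for pigment cells without control 3. The cell cycle list passed in each of these fits, and missed with quantile normalization (adjusted p 0.0507), as did complexes II to V (0.0507) and complex I (0.10). Pronephros missed with no minimum (0.0956) and with a minimum of 5 CPM (0.108). Without control 4 and canagliflozin 4 together the adjusted p was 0.149 for pigment cells and complex I and 0.191 for pronephros.

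Empagliflozin against canagliflozin compares related molecules at the same dose of 50 µM and the same time. Both are aryl C-glucosides; empagliflozin carries a chlorinated ring with an oxolanyl ether, and canagliflozin a methylated ring with a fluorophenyl-thiophene. Some lens and retina genes were higher with empagliflozin, and some respiratory chain, cell cycle, gluconeogenic and hypoxia-responsive genes were lower. As lists, the gluconeogenic one with glucose-responsive genes in it, these passed at the preset correlation, and with an estimated correlation 0 lists passed (adjusted p 0.258 to 0.558 for these). Other splits of these libraries gave up to 12 lists, so that chance is not excluded for the 9 that passed. atoh7 was at 9.51 ± 0.48 CPM with empagliflozin and 3.03 ± 0.402 with canagliflozin (n = 4 each), 2.62-fold higher on the CPM + 1 scale. ankrd37 was at 3.87 ± 0.511 and 12.1 ± 2.30 CPM, 2.66-fold lower on that scale. limma called 3049 of 11964 genes, 1485 higher and 1564 lower, of which 42 passed 2-fold on that scale. The pools of the groups did not overlap in 3059 genes (25.6%), against 2.86% by chance.

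The genes of largest difference held lens and eye genes on the higher side. crygm2d5 (Entrez 558470) differed by 1.51 on the log2 scale, with an interval of 1.14 to 1.88, and crygm2d12, crygm2d7 and crygm2d8 by 1.38, 1.33 and 1.32. atoh7 (Entrez 58216) differed by 1.39, with an interval of 0.84 to 1.94, crx by 1.21, the troponin gene tnnt2e by 1.31 and atxn1a by 1.18. In canagliflozin 4, crygm2d5 was -0.08 and atoh7 -0.23 from the other canagliflozin pools. mansc1 differed by 1.33, and in canagliflozin 4 it was 1.49 above the others. The ceruloplasmin gene cp differed by 1.26; its adjusted p was 0.0572 without empagliflozin 1, 0.068 without empagliflozin 2, 0.0746 without canagliflozin 1 and 0.067 without canagliflozin 2.

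Genes of several functions were on the lower side. ankrd37 differed by -1.41 (interval -1.68 to -1.15; limma adjusted p 4.28e-05), ctssb.1 by -1.26, mia by -1.25, cd36 by -1.11 and mogat2, a monoacylglycerol acyltransferase gene, by -1.09. rpa3, a subunit of replication protein A, differed by -1.08 and anapc16 by -1.16. In canagliflozin 4, rpa3 was -1.04 and anapc16 -0.44 from the other canagliflozin pools, and ankrd37 was 0.21. The authors' filtered table held 45 genes, 33 higher and 12 lower. Its members ccl27a (log2 1.251, adjusted p 0.152), tcap (-1.103, 0.251) and mmp13a (-1.06, 0.435) did not pass here.

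Some respiratory chain and cell cycle genes differed between the compounds. Of 35 genes of complexes II to V, 21 were lower and 0 higher, with a median of -0.32 (camera adjusted p 1.09e-06; adjusted p = 0.428 with an estimated correlation), and adjusted over the list alone 22 were lower. Of 35 complex I genes, 19 were lower and 1 higher, with a median of -0.28 (camera adjusted p 3.32e-05; adjusted p = 0.428 with an estimated correlation); adjusted over the list alone, 25 were lower and 1 higher. cyc1 differed by -0.49, cox7c by -0.74, sdhc by -0.68 and ndufa9a by -0.63. Of 28 cell cycle genes, 11 were lower and 1 higher, both over all genes and adjusted over the list alone, with a median of -0.13 (camera adjusted p 0.000423; adjusted p = 0.258 with an estimated correlation). The mitotic kinase genes aurkb and plk1 differed by -0.55 and -0.41, and the replication clamp gene pcna by -0.46. In canagliflozin 4 the medians of complex I, complexes II to V and cell cycle were -0.08, -0.09 and -0.06 from the other canagliflozin pools, against -0.31, -0.32 and -0.16 for empagliflozin.

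Some eye and neuron markers were higher with empagliflozin. Of 20 lens and retina genes, 10 were higher and 1 lower, with a median of 0.33 (camera adjusted p 9.49e-05; adjusted p = 0.558 with an estimated correlation), and adjusted over the list alone 14 were higher and 1 lower. six6b differed by 0.57, mipb, a lens water channel gene, by 0.52 and cryba4 by 0.47. The lower one was rx3, an early eye-field gene, at -0.43. Of 29 neuron markers, 11 were higher and 3 lower, with a median of 0.24 (camera adjusted p 0.00582; adjusted p = 0.553 with an estimated correlation), and adjusted over the list alone 12 were higher and 3 lower. cplx2 differed by 0.58 and stmn1b by 0.45. The 3 lower ones were phox2bb (-0.26) and the proneural genes neurog1 (-0.45) and ascl1a (-0.30). Neural progenitor and glia markers had a median of 0.19 and did not pass (adjusted p 0.178; 0.00434 with fry, which passed). In canagliflozin 4 the lens and retina median was 0.18 and the neuron median 0.20 above the other canagliflozin pools, against 0.38 and 0.20 for empagliflozin.

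Some genes of gluconeogenesis and of the hypoxia response were lower with empagliflozin. The list of gluconeogenesis and glucose-responsive genes, named the gluconeogenesis list below, held 14 measured genes, of which 6 were lower and 1 higher, with a median of -0.32 (camera adjusted p 0.0445; adjusted p = 0.428 with an estimated correlation), and adjusted over the list alone 7 were lower and 2 higher. pck1, encoding phosphoenolpyruvate carboxykinase, was at 18.3 ± 3.69 against 34.8 ± 10.6 CPM, a log2 difference of -0.87, and pck2 differed by -0.40. The glucose-6-phosphatase genes g6pca.1 and g6pca.2 differed by -0.83 and -0.70; the higher one was the pyruvate carboxylase gene pcxa, at 0.42. The glucose-responsive members txnipa, txnipb and mlx differed by -0.32, -0.45 and 0.16 and did not pass over all genes. Of 17 hypoxia-responsive genes, 6 were lower and 0 higher, with a median of -0.21 (camera adjusted p 0.0286; adjusted p = 0.258 with an estimated correlation), and adjusted over the list alone 7 were lower. ero1a differed by -0.56 and bnip3lb by -0.35. Against control the gluconeogenesis list had a median of -0.25 with empagliflozin (adjusted p 0.0714) and 0.02 with canagliflozin (0.394), and the hypoxia list -0.10 (0.0938) and 0.04 (0.15); with fry the adjusted p against control was 0.0222 and 0.00414 for these lists with empagliflozin, which passed. In canagliflozin 4 the medians of both lists were 0.02 and -0.02 from the other canagliflozin pools.

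Some myeloid and yolk markers were also lower. Of 14 myeloid markers 2 were lower, over all genes and adjusted over the list alone, with a median of -0.25 (camera adjusted p 0.0377; adjusted p = 0.469 with an estimated correlation); lcp1 differed by -0.56 and coro1a by -0.34. Of 19 yolk syncytial layer and liver markers 5 were lower, over all genes and adjusted over the list alone, with a median of -0.17 (camera adjusted p 0.0377; adjusted p = 0.734 with an estimated correlation). tfa differed by -0.84 and serpina1l by -0.61. In canagliflozin 4 the myeloid median was -0.03 and the yolk and liver median 0.17 from the other canagliflozin pools.

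The comparison between compounds moved less with single pools than the comparison with control. Its count fell to 1932 without canagliflozin 1, and without control 4 and canagliflozin 4 together 4887 genes passed. Lists that passed came to 5 of 9 without canagliflozin 4, where the adjusted p was 0.105 for the hypoxia and myeloid lists, 0.109 for gluconeogenesis and 0.195 for yolk and liver. They came to 5 with a minimum of 5 CPM, where it was 0.0614 for hypoxia, 0.0636 for yolk and liver and 0.0695 for the myeloid and gluconeogenesis lists. Without control 4 and canagliflozin 4 together it was 0.121 for the hypoxia and myeloid lists, 0.146 for gluconeogenesis and 0.223 for yolk and liver. With no minimum it was 0.0845 for gluconeogenesis and for yolk and liver, and with quantile normalization 0.0617 and 0.253. The gluconeogenesis list also missed without control 4 (0.0505), empagliflozin 2 (0.0709), empagliflozin 4 (0.0593) and canagliflozin 2 (0.0657). The myeloid list also missed without empagliflozin 1 (0.0542) and canagliflozin 2 (0.0657), and the yolk and liver list without empagliflozin 4 (0.13) and canagliflozin 2 (0.0657). Of 63 named genes that passed, 58 kept their call under every alternative. The authors' deposited table had 1861 genes under 0.05, of which 1694 were called here. Where the compounds did not differ past the threshold, the unadjusted intervals, of median half-width 0.22, give what a gene leaves open: for slc2a11b the difference was 0.06, with an interval of -0.10 to 0.22.

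**Figure D2:**
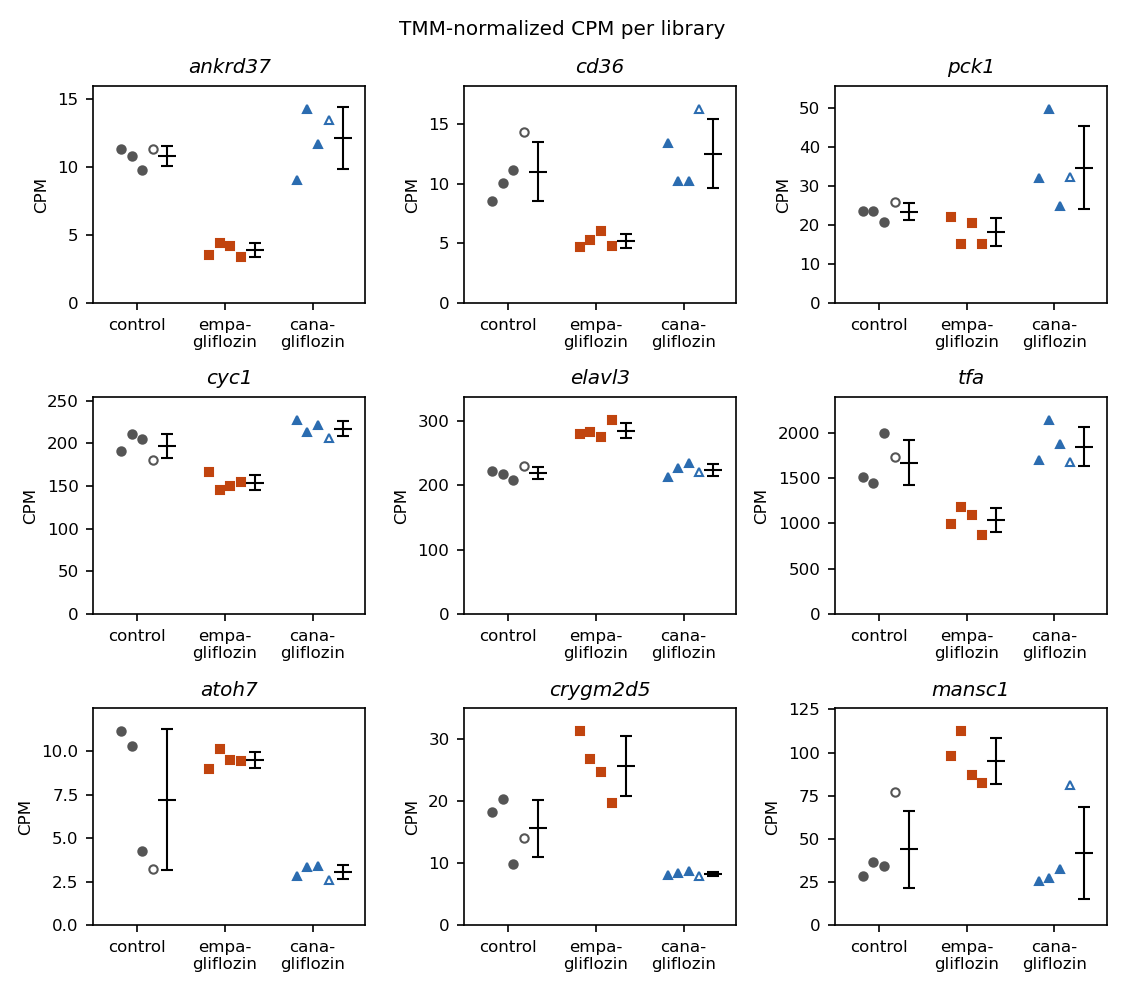
TMM-normalized CPM of 9 named genes in each library, by group, with the mean and SD of the 4 pools beside the points; open points are control 4 and canagliflozin 4. ankrd37 was at 3.87 ± 0.511 CPM in empagliflozin and 10.8 ± 0.734 in control, while mansc1 in control 4 stood 1.21 above the other controls on the log2 scale.

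**Figure D3:**
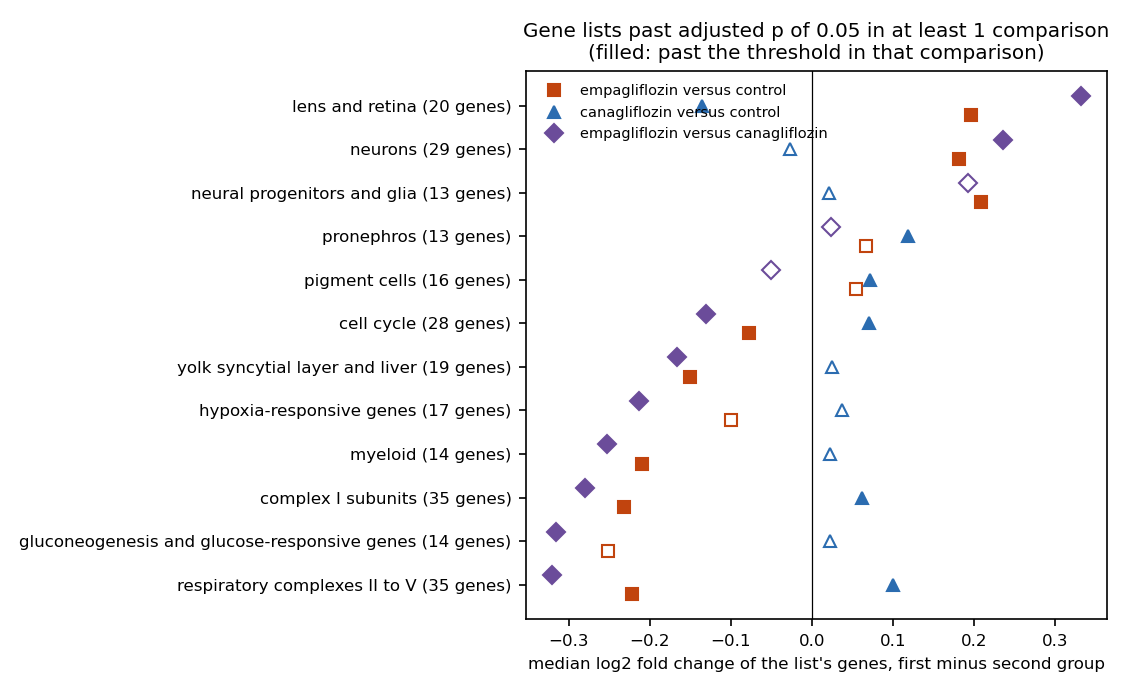
Median log2 fold change of each gene list that passed in at least 1 comparison; filled symbols passed camera at the preset correlation in that comparison, and 0 lists passed with an estimated correlation. Complexes II to V lay at -0.22 against control and -0.32 against canagliflozin in empagliflozin.

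The genes called for empagliflozin overlapped between its comparisons. Of 822 genes higher than in control, 682 were also higher than in canagliflozin, where 102 would be shared by independent lists. Of 767 lower than in control, 652 were also lower than in canagliflozin, against 100.3, and 0 genes were called in opposite directions. The comparisons share the empagliflozin pools, which by itself raises such an overlap.

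A response shared by the compounds was not detectable. Across 11964 genes, which are not independent replicates, the log2 fold changes of the compounds against the same controls correlated at -0.0414, with a covariance of -0.00133. Simulated unchanged groups against shared controls gave a correlation of 0.499 (0.462 to 0.527) with independent genes. With the correlation between genes kept, simulated values ran from -0.677 to 0.960, and 12 of 100 draws lay at or below the observed value. With the controls split between the compounds, over 6 splits, the mean was -0.227 (-0.432 to 0.0589).

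The drug target and related transporters had few reads or small differences. slc5a2 had 0 to 7 reads per library and slc5a1, which encodes SGLT1, had 2 to 16, so that both lay under the minimum and were not tested. In control slc5a2 was at 0.203 ± 0.125 CPM, with empagliflozin at 0.104 ± 0.177 and with canagliflozin at 0.122 ± 0.0573. slc2a5 had a mean of 0.0146 CPM in control and was read at 0 in both treated groups. Of the 8 measured genes in the glucose transporter list, 0 passed with empagliflozin against control, over all genes or adjusted over the list alone, with a median of -0.15 (adjusted p 0.497). With canagliflozin 0 passed, with a median of 0.02 (adjusted p 0.581); the glucose transporter gene slc2a1a was at 32.9 ± 2.88 against 25.7 ± 4.66 CPM (log2 0.36, adjusted p 0.529). Between the compounds the list did not pass (adjusted p 0.29; 0.0220 with fry, which passed), and 2 of the 8 were lower, over all genes and adjusted over the list alone: slc2a1a by a log2 of -0.33 (adjusted p 0.0488) and slc2a10 by -0.31 (adjusted p 0.0405). Outside the list, slc2a15b was lower with empagliflozin than in control (-0.28, adjusted p 0.0449) and than with canagliflozin (-0.27, adjusted p 0.0335).

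Calls in these transporters hung on single pools. Against control, the adjusted p of slc2a15b was 0.12 without control 1, 0.09 without control 2, 0.118 without control 3, and 0.128, 0.0757 and 0.101 without empagliflozin 2, 3 and 4. It was 0.0539, 0.0571 and 0.0512 without canagliflozin 1, 2 and 3. Between the compounds it was 0.108, 0.051 and 0.0803 without empagliflozin 2, 3 and 4, and 0.0896, 0.0626 and 0.102 without canagliflozin 1, 2 and 3. For slc2a1a it was 0.052 without control 2, 0.131, 0.0891 and 0.104 without empagliflozin 2, 3 and 4, and 0.108, 0.134 and 0.0505 without canagliflozin 1, 2 and 3. For slc2a10 it was 0.0513 without control 2, 0.10, 0.0513 and 0.112 without empagliflozin 1, 3 and 4, and 0.077 and 0.119 without canagliflozin 2 and 3.

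The other lists passed in no comparison, with smallest adjusted p of 0.168 for empagliflozin against control, 0.064 for canagliflozin against control and 0.0642 between the compounds. Their medians follow in that order of comparisons. Glycolysis genes had medians of -0.08, 0.01 and -0.21, with 10 lower and 3 higher between the compounds. Insulin and insulin-like growth factor signalling had 0.09, -0.04 and 0.19, the integrated stress response -0.06, 0.02 and -0.08, and endoplasmic reticulum chaperones 0.04, -0.02 and 0.02. Cholesterol synthesis had -0.01, 0.06 and -0.09, fatty acid synthesis 0.04, 0.03 and 0.11, and fatty acid oxidation -0.07, -0.02 and -0.05. Heat shock proteins had -0.14, -0.03 and -0.13, the oxidative stress response -0.06, 0.03 and -0.01, xenobiotic metabolism -0.13, 0.01 and -0.07, and p53 targets -0.02, -0.02 and 0.00. Immediate early genes had -0.10, -0.06 and -0.02, glucocorticoid-responsive genes -0.06, -0.14 and 0.13, the circadian clock 0.06, -0.04 and 0.09, and sodium and proton transport 0.01, -0.00 and -0.03. Inflammation and interferon genes had -0.30, -0.06 and -0.36, with all 13 lower on average with empagliflozin than in control and 0 passing. The control mean rests in part on control 3, where mmp9 was at 92.0 and irg1l at 78.4 CPM. The other controls had at most 13.7 and 9.89 CPM of these genes.

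Lists of further cell types did not pass in the comparisons given here. Heart had medians of 0.08, 0.01 and 0.01, skeletal muscle -0.04, -0.07 and 0.06, erythroid cells -0.12, -0.11 and -0.04, and endothelium 0.07, 0.07 and 0.01. The hatching gland had 0.07, -0.10 and 0.24, epidermis and ionocytes 0.00, -0.02 and -0.09, and notochord and cartilage 0.09, -0.04 and 0.14. Segmentation and tailbud genes, which change with embryonic age, had 0.03, 0.02 and -0.05. Pigment cells had 0.05 and -0.05, and pronephros 0.07 and 0.02, in the comparisons with empagliflozin, and did not pass there. Neurons had -0.03, neural progenitors 0.02, myeloid cells 0.02 and yolk and liver 0.02 with canagliflozin against control, and did not pass. The sign of the median and that of the test or mean differed for sodium and proton transport, segmentation, epidermis and cholesterol synthesis in empagliflozin against control. The same held for xenobiotic metabolism, fatty acid synthesis and sodium transport in canagliflozin against control, and for p53 targets, endothelium, epidermis and pronephros between the compounds.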

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

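All tests in this part were chosen after the results were seen. Sets of 4 values, such as the CPM of a named gene in the 4 libraries of a group, were screened with Dixon's outlier test. Of 429 sets, 31 held a value far from the other 3, with 12 in canagliflozin 4 and 7 in control 4. A rate of about 1 in 20 would give 21.5. That figure is not a valid chance expectation here. Many named genes were chosen from the same data, and genes of a library are not independent.

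Control 4 and canagliflozin 4 lay between their groups and empagliflozin. A mislabelled empagliflozin library would stand with that group on the scale from its labelled group to empagliflozin. But control 4 stood at 0.677, where the empagliflozin libraries stood at 0.877 to 0.967. Canagliflozin 4 stood at 0.534, where they stood at 0.880 to 0.9749. Single genes went both ways. In control 4 and canagliflozin 4 ankrd37 was at 11.3 and 13.4 CPM, against 3.36 to 4.41 in empagliflozin. There rbmx2 was at 57.1 and 50.1 CPM, within the empagliflozin range of 47.6 to 67.5. A batch shared by the libraries numbered 4 would tie them to empagliflozin 4, but the higher of its correlations with them, in deviations from group means across genes, was 0.0651. Control 4 and canagliflozin 4 correlated with each other at 0.592, so that an origin they share and the labels do not record, such as a clutch or a stage, may account for them. Control 4 was in DMSO and still stood at 0.677 toward empagliflozin. The same kind of origin could therefore also lie under the empagliflozin pools and the genes called for them. Deviations from group means cannot show an origin that all empagliflozin pools share. The design holds no group that tells such an origin from chance or from the compound, and no biological explanation was tested.

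A part of the respiratory chain genes was lower in empagliflozin. Lower recovery of short transcripts would lower the short Sm and LSm genes alike; their change was above that of the respiratory chain by 0.213 on the log2 scale against canagliflozin (exact permutation p 0.0286, unadjusted) and by 0.129 against control (exact permutation p 0.143). Ribosomal protein genes, also short, had medians of -0.36 and -0.21, which goes with lower recovery, so that it stays open in both comparisons. On complex I, control 4 and canagliflozin 4 lay toward empagliflozin, at medians of -0.20 and -0.08 from the rest of their groups. Empagliflozin lay at -0.29 and -0.31 from the same pools. Complexes II to V were alike, at -0.19 and -0.09 in these libraries. Leaving both out could therefore not remove the difference. The highest camera adjusted p without them, 0.00131 at the preset correlation, is no independent support. With all libraries and an estimated correlation neither list passed (camera adjusted p 0.428 to 0.462). A different make-up of cell types cannot be told apart from a change within cells, since neuron markers moved too (median 0.181), so that an effect of the compound on mitochondrial transcripts is a hypothesis only.

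Several lens and retina genes were higher in empagliflozin than in canagliflozin. The crygm2d crystallins, which are not in the lens and retina list and were picked after the data were seen, were higher too. Reads divided differently among these near-identical copies would leave their sum alike. The summed crygm2d CPM differed by 1.07 on the log2 scale (exact permutation p 0.0286, unadjusted), at 387 to 493 against 196 to 230. In control it was 244 to 434, which overlapped empagliflozin and not canagliflozin. The sum speaks for this family alone and does not test the list. The list passed without control 4 and canagliflozin 4 (camera adjusted p 0.000601 at the preset correlation). Canagliflozin 4 lay toward empagliflozin, at a median of 0.18 from the other canagliflozin pools, against 0.38 for empagliflozin. Leaving it out could therefore not remove the difference. With all libraries and an estimated correlation the list did not pass (camera adjusted p 0.558). A difference in embryo age may take part: the segmentation and tailbud median was -0.051, over members from -0.348 to 0.368 that went both ways, and cannot decide it. An effect of either compound on lens genes therefore stays a hypothesis beside age.

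Other splits of the 8 libraries of a comparison were counted. For empagliflozin against control, 1 of 35 splits, the real one, gave 1589 genes, and the highest other gave 253, with control 4 and empagliflozin 4 exchanged. For empagliflozin against canagliflozin, 1 of 35 gave 3049 and the highest other 3. A share of 1 in 35 is the smallest that 35 splits can give, so that chance is unlikely for both counts but not excluded. Both comparisons share the empagliflozin pools, so that these counts are not separate support. The splits treat pools as interchangeable and cannot tell a compound from an origin that the labels do not record. At an unadjusted limma p under 0.05 the margins were smaller. Against control the real split gave 3874 genes and others up to 2858, and against canagliflozin 4693 and up to 2896. For canagliflozin against control the real count was 0 (limma; 925 at an unadjusted p under 0.05; edgeR 0, DESeq2 24), which all 35 of 35 splits reach by construction, so that nothing follows from it on chance. The highest other gave 27, in a split that sets control 3 and the 3 canagliflozin libraries other than 4 against the rest, which points to a structure of the samples. List counts could all come by chance: 11 of 35 splits gave at least 8 lists (highest other 15), 19 of 35 gave at least 6 (highest other 14) and 7 of 35 gave at least 9 (highest other 12).

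In control 4, mansc1 was at 77.1 CPM (other controls 28.2 to 36.4), gpatch3 at 40.6 (22.5 to 25.1), plgrkt at 68.1 (36.98 to 40.7) and rbmx2 at 57.1 (25.9 to 27.9). pax6b was at 38.6 there (27.7 to 29.3), rpa3 at 19.3 (36.6 to 38.3) and ndufab1b at 39.5 (54.3 to 56.5). In canagliflozin 4, mansc1 was at 81.4 CPM (other canagliflozin pools 25.8 to 32.5), and3 at 96.8 (at most 45.1), gpatch3 at 40.7 (22.5 to 23.5) and tnni2a.2 at 13.8 (5.09 to 5.71). plgrkt was at 79.3 there (32.7 to 36.2), rbmx2 at 50.1 (22.9 to 25.1), igfbp7 at 33.7 (18.6 to 19.6) and zgc:173593 at 26.8 (8.24 to 10.1). neurog1 was at 89.1 in that library (65.5 to 68.6), snrpc at 108 (94.8 to 96.4), cox6a1 at 281 (203 to 215) and mcm3 at 240.1 (272 to 274).

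In the other controls, rasd1 was at 41.5 CPM in control 1 (27.7 to 29.3 in the rest of the group) and ap1ar at 9.80 in control 2 (10.9 in each of the rest). In control 3, clcnk was at 5.89 (3.46 to 3.52), si:ch211-117m20.5 at 129.9 (72.4 to 75.9), tcap at 19.5 (1.63 to 3.63) and mmp13a at 50.4 (0.876 to 1.97). crygm2d21 was at 19.7 in canagliflozin 2 (16.7 to 17.1). In empagliflozin 1, raph1b was at 83.8 (101.1 to 103) and apoa4a at 33.95 (29.8 to 30.02). pttg1 was at 10.96 in empagliflozin 2 (8.73 to 8.93), mmp13a at 11.7 in empagliflozin 3 (0.436 to 1.204) and bnip3lb at 39.9 in empagliflozin 4 (33.4 to 34.1).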

How the results depend on the processing

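Leaving out control 4 and canagliflozin 4 together, and median centring for the lists, were chosen after the results were seen; the other alternatives were planned. No named gene or list past the threshold reversed, and all genes called against control kept their sign. Gene counts moved by over 1.5 times for empagliflozin against control with sample weights (4476), at an adjusted p of 0.1 (2870, by construction) and without control 4 and canagliflozin 4 (4246), and from 268 to 3033 with 1 library left out. For canagliflozin against control they came to 42 with sample weights, 24 with DESeq2 and 0 to 7 with 1 library left out. Between the compounds they came to 5464 with sample weights, 4887 without control 4 and canagliflozin 4, and 1932 to 4234 with 1 library left out. Sample weights gave control 4 and canagliflozin 4 the lowest weights, 0.332 and 0.237. Other gene alternatives stayed within 1.5 times. Lists that passed were 0 in each comparison with an estimated correlation. They were 5 with quantile normalization, 3 without control 4 and canagliflozin 4 and 3 to 10 with 1 library left out for empagliflozin against control, and 1 with fry and 2 to 10 with 1 library left out for canagliflozin against control. Between the compounds they were 5 at a minimum of 5 CPM, 5 without control 4 and canagliflozin 4 and 5 to 10 with 1 library left out. Except where named, the cause was not tested.

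The replicate numbers did not pair the libraries: deviations of libraries with the same number correlated from -0.125 to 0.592, with a median of -0.0114, and 3 of 12 libraries lay closest to one of their own number. With the number as a block, 2269, 0 and 3456 genes and 7, 7 and 8 lists passed in the order above, where cell cycle against control (adjusted p 0.0574) and gluconeogenesis and glucose-responsive genes between the compounds (0.0560) were lost.

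Among values of named genes under alternatives that kept all libraries or left out both libraries, empagliflozin against control had 899 on the same side of the threshold, 33 no longer past it and 29 newly past it. Between the compounds these were 1025, 9 and 10, and for canagliflozin against control 688, 0 and 36. With 1 library left out they were 668, 153 and 7, then 861, 33 and 6, then 617, 0 and 7. The observed correlation of both responses stayed between -0.08 and -0.01 with a pseudocount of 0.1, a minimum of 5 CPM or quantile normalization, and was -0.227 with the controls split between the compounds. At this depth 1 read was 0.0363 to 0.0621 CPM, which limits what can be said of slc5a2, with 0 to 7 reads per library.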

Other observations

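The tests of gene families in this part were chosen after the results were seen. Some genes of protein synthesis and turnover also fell in empagliflozin. Of 78 cytosolic ribosomal protein genes, 32 fell and 1 rose against control (median log2 change -0.21), and 50 were lower and 1 higher than with canagliflozin (-0.36); with canagliflozin against control the median was 0.12 and 0 passed. Of 15 genes of the proteasome core, 7 fell against control (-0.23) and 9 were lower than with canagliflozin (-0.26). The family means of all 4 empagliflozin libraries lay below all 4 of the other group in these comparisons, at an exact permutation p of 0.0286, the smallest possible, and 0.0612 after adjustment over 15 such tests, which does not pass. Genes of Sm and LSm proteins, of RNA splicing and decay, had medians of -0.07 and -0.02. Directions held under quantile normalization and median centring.

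Some collagen genes went the other way. Of 24 measured, 6 rose and 1 fell with empagliflozin against control (median 0.18; exact permutation p 0.0571, adjusted 0.107), and 13 were higher and 1 lower than with canagliflozin (0.34; exact permutation p 0.0286, adjusted 0.0612), while canagliflozin against control had a median of -0.13. Of 18 crygm2d genes, 6 rose with empagliflozin against control (0.29; exact permutation p 0.257, adjusted 0.321), 15 were higher than with canagliflozin (0.97; exact permutation p 0.0286, adjusted 0.0612), and 0 passed with canagliflozin against control (-0.64; exact permutation p 0.0286, adjusted 0.0612). No family passed after adjustment. These directions too held under quantile normalization and median centring.

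The list of inflammation and interferon genes, 13 measured, passed in no comparison, and its mean log2 level was 4.78 in control 3, 4.03 in canagliflozin 1 and in canagliflozin 2, 3.86 in empagliflozin 3 and 2.77 to 3.26 in the other 8 libraries. Of its members, 3 picked after the data were seen follow. mmp9 was at 92.0 CPM in control 3, 51.5 in empagliflozin 3, 67.2 in canagliflozin 1 and 52.3 in canagliflozin 2, and at 4.87 to 13.7 in the other 8 libraries. irg1l was at 78.4 CPM in control 3, 28.1 in canagliflozin 2, 13.9 in empagliflozin 3, 9.89 in control 2 and 9.19 in canagliflozin 1, and at 1.38 to 4.12 in the others. il1b was at 4.49 CPM in control 3, 2.83 in empagliflozin 3, 2.64 in canagliflozin 1 and 1.37 in canagliflozin 2, and at 0.251 to 0.625 in the others. zgc:158463 was at 5553 CPM in canagliflozin 2 and 4590 in canagliflozin 3, beside 851 and 1073 in the other canagliflozin pools.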
